A study of Homo sapiens with 3 samples.

How the data were processed

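RNA sequencing of polyA+ RNA was carried out on 3 libraries of UM-UC-3, an established human bladder cancer cell line. Per the labels' protocols, cells were infected with lentivirus that expressed either a scramble short hairpin RNA or 1 of 2 hairpins against the long non-coding RNA BLACAT2, were kept under puromycin, and gave total RNA that was made into libraries with a TruSeq stranded mRNA kit. The scramble library forms the group shControl (n = 1). The libraries of shRNA 1 and shRNA 2 form the group shBLACAT2 (n = 2) as its replicates 1 and 2, each hairpin being represented by 1 library.

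The deposited table gives, per gene, whole-number read counts and FPKM values made by the authors, with 1 column of each per library. Per the submitters' processing notes, TopHat2 2.0.9 and the build hg38 were used; the counting tool, its strand setting, the gene annotation release and any filter are not given in the sources used here. FPKM is a count divided by gene length and library total. Between libraries the deposited FPKM of a gene moved by 1 constant times its count, between 1.07579 and 1.07586 for the control over shRNA 1 and between 0.98731 and 0.98738 for the control over shRNA 2, over 13333 genes with more than 20 counts. FPKM therefore added nothing to a comparison between libraries, and the counts were used throughout. Because strand use is not stated, genes that overlap an antisense partner, and genes with near-identical copies such as keratins, kallikreins, interferon lambda genes, HLA genes and histone genes, may share reads and are uncertain.

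The table held 50871 lines after its header. The row of 1 gene, TGFB1, was broken over 4 lines and was left out, which left 50867 genes, of which 19696 had no count in any library. The gene identifiers of 50110 of them (98.5%) were found in GENCODE release 29, and 99.99% of these lay on the same chromosome at an overlapping position. Gene types come from that release. Positions are those of the deposited table on hg38. Library totals were 16424422 counts for the control, 17670199 for shRNA 1 and 16216947 for shRNA 2. A gene with 0 counts was set against a floor of 3 counts, which corresponds to 0.198, 0.168 and 0.174 TMM-scaled CPM in these libraries. Intervals at the 95% level are exact conditional binomial intervals of a ratio of counts, except those of list and chromosome medians. These count intervals and the floors cover counting error only, since the reads carry no molecular identifiers. Intervals of list and chromosome medians come from a bootstrap over genes. It treats genes as independent and leaves out the spread between libraries.

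Genes with a mean of at least 1 CPM over the 3 libraries were tested (15132 genes). Counts were scaled with edgeR's TMM factors (0.924 for the control, 1.02 for shRNA 1 and 1.07 for shRNA 2), and log2 folds over the control were taken from log2 CPM with a prior count of 2. A gene was counted as at least 2-fold higher or lower when both hairpins gave that size in the same direction. The group test was edgeR's quasi-likelihood test of both shBLACAT2 libraries against the control, two-sided, with Benjamini-Hochberg adjusted p below 0.05. It has 1 residual degree of freedom, which measures the spread between the hairpin libraries, and the lone control is assumed to vary like them. Nothing in the labels says that the libraries came from repeated cultures, so its p-values measure the spread between these libraries only. The correlation of both hairpins' folds was set beside 100 simulations in which unchanged libraries shared 1 control, with noise drawn from the difference between the hairpin libraries in 30 bins of mean expression. The single control could not be split.

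A set of 34 gene lists (690 genes, 627 measured) was written from textbook knowledge before the data were examined, as were the tests, the naming rule and the other settings described below. For each list and hairpin, the median log2 fold was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. To account for the shared control, the number of lists outside with both hairpins was also computed for 10000 sets of random lists that held the same genes for both, a check added after the data were seen. The percentile describes these libraries and is not a p-value. Numbers of list members that passed edgeR's test are given over all genes and adjusted over the list alone. Genes were named by rule: LINC00958 and VEGFC always, the 10 highest and 10 lowest genes by the smaller of both log2 folds among genes at least 2-fold higher or lower with both hairpins (unnamed, clone-named, pseudogene, microRNA and snoRNA features were skipped), and per list up to 4 members past that size or, with none, up to 2 members of highest mean expression. Further genes are named as chosen after their values were seen.

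The results were also computed with DESeq2's size factors and library totals as the scaling, no low-expression filter or a mean of at least 5 CPM, prior counts of 0.5 and 5, sizes of 1.5-fold and 3-fold, DESeq2 and limma with a trended variance as other tests, and leaving out each hairpin. The software was R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

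The tests were checked on simulated counts for the same comparison of both hairpins with 1 control, over 15132 genes with 50 genes changed at each of 4 sizes and a dispersion trend taken from the real libraries, without scatter of single genes around it. At 2-fold, 4-fold, 16-fold and 64-fold, edgeR found 8%, 44%, 90% and 94% of the changed genes and called 9 unchanged genes. The 2-fold size rule found 40%, 82%, 100% and 100% of them and also took in 788 unchanged genes. In the real libraries 10 genes were at least 16-fold higher and 48 at least 16-fold lower with both hairpins. Of all genes tested there, edgeR passed 6, so its simulated shares do not carry over to these libraries. Of 100 simulated lists of 25 genes without a shift, 5 fell outside the middle 95% of random lists, and a shift of 0.50 on the log2 scale was found in 99 of 100. The simulated lists were themselves drawn at random, so the share outside follows from the design. Lists of genes that move together are not covered by this check.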

Results

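Expression was measured by RNA sequencing in UM-UC-3 bladder cancer cells that carried a scramble hairpin (shControl, n = 1) or either of 2 hairpins against BLACAT2 (shBLACAT2 replicates 1 and 2, n = 2, called shRNA 1 and shRNA 2 here). The series looked for genes that depend on this long non-coding RNA. The libraries held 16424422, 17670199 and 16216947 counts. The fibronectin gene FN1 alone took 5.53% of the counts in the control and 1.72% and 1.67% with shRNA 1 and shRNA 2. Transcripts of the mitochondrial genome took 3.88%, 4.58% and 2.51% in the same order.

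The target RNA itself was compared first. BLACAT2 is listed under its symbol LINC00958 (ENSG00000251381; hg38, chromosome 11, 12961842 to 12989548, minus strand), an intergenic long non-coding RNA gene with 7 annotated transcripts. It had 938 counts in the control, 816 with shRNA 1 and 1062 with shRNA 2. Scaled for library size, the library labelled shRNA 1 held 73.5% of the control level (ratio 0.735, 95% counting interval 0.668 to 0.808), and the library labelled shRNA 2 held 99.6% of it (ratio 0.996, interval 0.911 to 1.09). The mean log2 fold was −0.22 ± 0.31 (SD, n = 2), smaller than the spread between the hairpins, and edgeR gave an adjusted p of 0.913. The design text states that the knockdown was measured by quantitative RT-PCR, and those values are not analysed here. In these counts the depletion that the labels name was not detected with shRNA 2. Every direction given below is therefore that of a library labelled with a hairpin, and not of a measured loss of the RNA. Of the genes near LINC00958, RASSF10 was lower with both hairpins (log2 folds −1.02 and −2.24), and TEAD1, which was chosen after its values were seen, had 6107 counts in the control, 6863 with shRNA 1 and 7011 with shRNA 2 (scaled log2 folds −0.07 and 0.01).

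**Figure D1:**
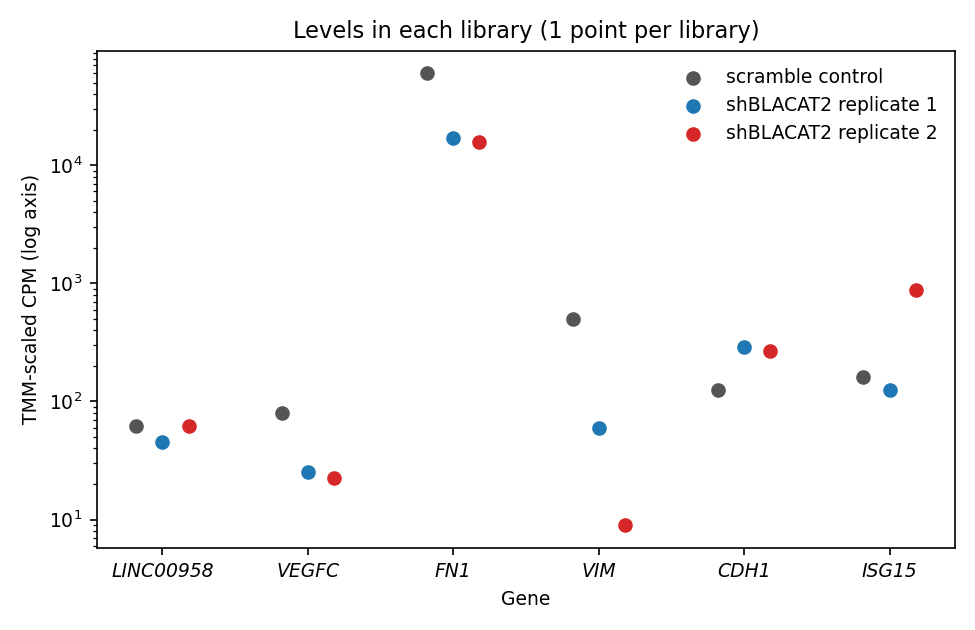
TMM-scaled CPM on a log axis for LINC00958, VEGFC, FN1, VIM, CDH1 and ISG15, with 1 point per library and no error bars, since each hairpin and the control has 1 library. LINC00958 lay at 62.0, 45.6 and 61.7 CPM in the control, shRNA 1 and shRNA 2 libraries, while VEGFC lay at 79.6, 25.1 and 22.4 CPM.

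VEGFC encodes a growth factor of lymphatic vessels, and was chosen for its own comparison before the data were examined. VEGFC (ENSG00000150630; chromosome 4, 176683538 to 176792727) was lower in both libraries labelled with a BLACAT2 hairpin, with 1205 counts in the control, 449 with shRNA 1 and 386 with shRNA 2. This was 3.18-fold lower (ratio 0.315, 95% counting interval 0.282 to 0.351) and 3.55-fold lower (ratio 0.282, interval 0.251 to 0.316). Other secreted factors of lymphatic vessel growth and their processing were also lower: PDGFB (log2 folds −2.40 and −2.85), the co-receptor NRP2 (−2.49 and −1.88) and IGF2 (−2.45 and −1.86). Of 12 measured members of that list, 6 were at least 2-fold lower with both hairpins and none was higher by that size. The median log2 folds were −1.37 and −1.53, below all 10000 random lists with either hairpin. The VEGF ligands and receptors as a list had medians of −1.20 with shRNA 1 (percentile 0.01 among random lists) and 0.40 with shRNA 2 (percentile 89.7), with VEGFA, chosen after its values were seen, at −0.46 and 0.80.

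The VEGFC fold of −1.74 ± 0.11 (SD, n = 2) was larger than the difference between the hairpins but did not pass the group test over all genes, with an edgeR log2 fold of −1.74 (SE 0.30) and adjusted p = 0.132. DESeq2 gave an adjusted p of 0.0116, and over all tests run it ranged from 0.0116 to 0.747. Adjusted over the list alone, edgeR passed 3 of the 12 lymphatic factors and 2 of the 8 VEGF genes, and none of either over all genes tested. WDR5, a subunit of the histone H3K4 methyltransferase complex, was chosen after its values were seen and had log2 folds of 0.07 and 0.34. The 17 genes of this complex had medians of −0.06 and −0.01, and none passed the size rule. KMT2A (−0.06 and 0.13) and WDR82 (−0.36 and −0.51) had the highest mean levels among them.

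Across all genes, the genes furthest below the control in both libraries labelled with BLACAT2 hairpins came from several functional groups. IGFBP5, an insulin-like growth factor binding protein, had 6522 counts in the control and 29 and 12 with the hairpins. The collagen COL22A1 had 1751, 16 and 22, the gelatinase MMP2 9383, 202 and 48, and the antisense RNA APCDD1L-AS1 1003, 20 and 19. C4orf26 (878, 19 and 16), HHIP (670, 18 and 5), MEDAG (392, 8 and 3), the BMP-family ligand GDF6 (318, 1 and 4), the adhesion protein gene CNTN1 (283, 4 and 1) and the gap junction gene GJA1 (268, 4 and 1) completed the 10 lowest. In the other direction, the activin subunit gene INHBB had 16 counts in the control and 1523 and 2369 with the hairpins, 80.4-fold and 130-fold higher. GDA (36, 2204 and 1193), MACC1 (126, 3101 and 2400), the mucin MUC16 (102, 2828 and 1940) and the kallikrein KLK7 (6, 310 and 193) were higher, as were KLK8 (3, 195 and 146; ratio with shRNA 2 of 42.8, counting interval 14.4 to 210) and the tryptophan-degrading enzyme gene IDO1 (3, 295 and 94; ratio with shRNA 2 of 27.6, interval 9.14 to 136). SCEL, MPPED1 and KCNB2 had 0 counts in the control. Set against the floor of 3 counts, they were at least 32.4-fold, 30.1-fold and 11.6-fold higher with shRNA 1, and the lower 95% counting bounds were 25.9, 24.1 and 8.98. With shRNA 2 they were at least 55.4-fold, 14.4-fold and 13.8-fold higher, with lower bounds of 44.6, 11.2 and 10.8.

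By edgeR's test 6 of 15132 genes passed, all lower: COL22A1, APCDD1L-AS1, IGFBP5, C4orf26, NREP and MMP9, each at adjusted p = 0.0458. NREP fell by 5.17 (SE 0.37) and MMP9 by 5.55 (SE 0.40) on edgeR's log2 scale. INHBB, MACC1 and MUC16 each stood at an adjusted p of 0.0696. An unadjusted p below 0.05 was found for 1549 genes. With DESeq2, 531 genes passed, 238 higher and 293 lower, and these included the 6 genes. By size, 1481 genes (9.79%) were at least 2-fold away from the control with both hairpins, 800 higher and 681 lower, and for 1359 of them the smaller fold exceeded the difference between the hairpins. With shRNA 1 alone, 2315 genes reached that size (1199 higher, 1116 lower), and with shRNA 2 alone 3286 did (1961 higher, 1325 lower). Library totals as the scaling put the median log2 fold of all genes at 0.14 and 0.24, against 0.01 and 0.04 with TMM. They gave 1031 genes higher and 553 lower with both hairpins. No gene passed without the low-expression filter (1461 genes at unadjusted p below 0.05), with the filter at 5 CPM (1240) or with limma (1560), against 531 with DESeq2 and 6 with edgeR, and the count by size was 2805 without the filter and 979 with it at 5 CPM.

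**Figure D2:**
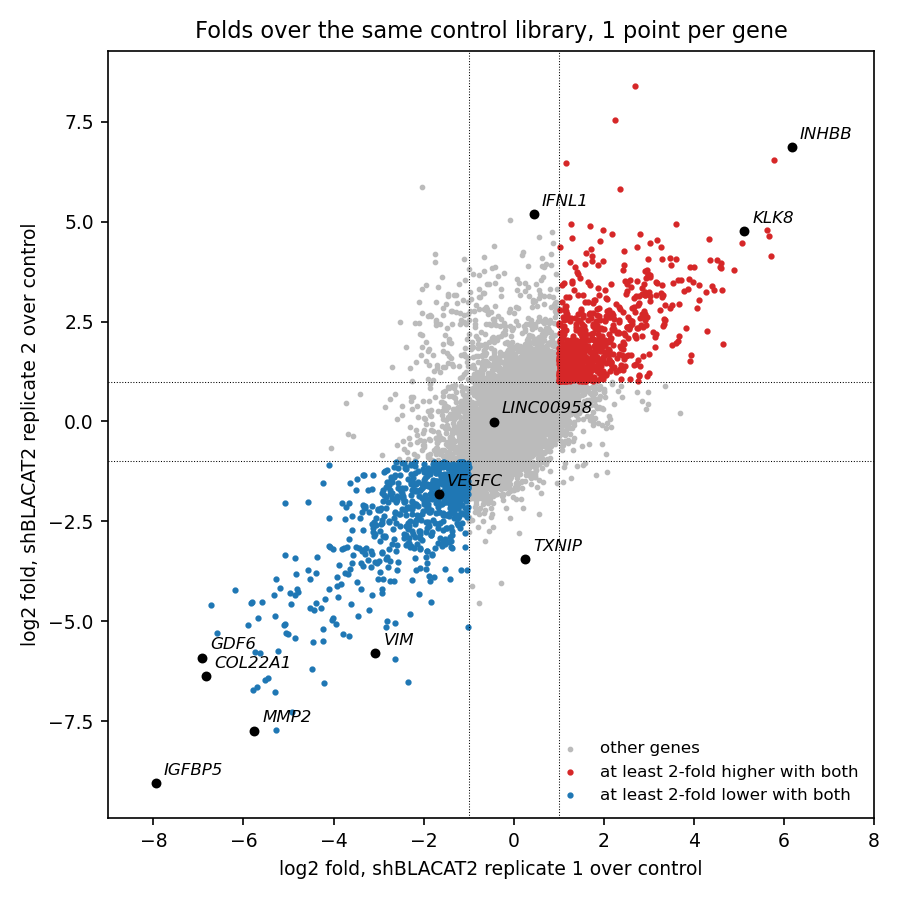
Log2 folds over the control with shRNA 1 (horizontal axis) and shRNA 2 (vertical axis), with 1 point per tested gene, dotted lines at 2-fold and both folds taken over the same control library. Red points are the 800 genes at least 2-fold higher and blue points the 681 at least 2-fold lower with both hairpins, VEGFC among the latter, while LINC00958 lies near the centre.

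Mesenchymal genes were lower as a group in both libraries labelled with BLACAT2 hairpins. Of 30 measured genes of mesenchymal state and epithelial to mesenchymal transition, 25 were at least 2-fold lower with both hairpins, 1 (S100A4) was higher by that size, and 4 were neither. MMP2 had log2 folds of −5.77 and −7.74, MMP9 −5.23 and −5.75, N-cadherin CDH2 −4.93 and −7.28, and the matrix protein gene TGFBI −4.49 and −6.18. The median was −2.50 and −2.93, below all 10000 random lists. edgeR passed 26 of the 30 when adjusted over the list alone and 1, MMP9, over all genes tested. Among 24 targets of YAP, TEAD and TGF-beta signalling, 10 were at least 2-fold lower and none higher, with THBS1 at −4.00 and −4.91 and TGFB2 at −4.57 and −3.72. Their medians were −0.64 and −1.40, and 10 passed when adjusted over the list alone.

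Integrins and adhesion receptors were mostly lower, 7 of 21 by at least 2-fold with both hairpins, with ITGB3 at −4.79 and −4.27 and ITGA5 at −2.32 and −2.16. ITGB8 alone was higher by that size, at 3.30 and 3.10. The list medians were −0.81 and −0.70. Hypoxia-inducible genes had medians of −0.61 and −1.03, and 9 of 26 were at least 2-fold lower, among them the lysyl oxidase gene LOX (−4.96 and −4.29), ANGPTL4 (−2.81 and −5.00), NDRG1 (−2.75 and −3.48) and P4HA2 (−1.69 and −1.98). Adjusted over the list alone, 6 integrin-list genes and 5 hypoxia genes passed, and none over all genes. Of 5 measured markers of fibroblasts and smooth muscle, COL1A1 (−4.24 and −5.19), PDGFRB (−3.41 and −2.40) and FAP (−3.60 and −2.36) were lower with both hairpins, while ACTA2 (−0.23 and 1.27) was at least 2-fold higher with shRNA 2 and MYH11 (−0.57 and −0.07) was neither (both chosen after their values were seen), with medians of −3.41 and −2.36 over these markers of 12 listed, and 3 passed adjusted over the list alone. COL1A1 also stands in the mesenchymal list. COL1A2, COL3A1, DCN and LUM had 16, 20, 2 and 2 counts in the control, against 5253 for COL1A1.

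Epithelial and luminal urothelial genes were higher as a list in the same libraries. Of 22 measured, 8 were at least 2-fold higher with both hairpins and none lower by that size. GRHL3, a transcription factor of surface epithelia, had log2 folds of 3.33 and 3.16, the claudins CLDN3 and CLDN7 3.03 and 3.02 and 1.72 and 1.75, and the epithelial transcription factor gene ELF3 2.80 and 2.58. E-cadherin, CDH1, chosen after its values were seen, had 1.23 and 1.10. Other epithelial genes, chosen in the same way, were not all higher. EPCAM had 0.79 and 0.28, KRT8 0.16 and −0.51, KRT7 −0.22 and −0.78, and DSP −2.47 and −1.92. The list medians of 1.00 and 0.88 lay above all 10000 random lists, and 5 members passed edgeR's test adjusted over the list alone and none over all genes. Basal and squamous genes had medians of −0.83 and −0.48 (percentiles 0 and 2.27). In that list TP63, a basal transcription factor, was at −3.34 and −2.71, and KRT6A and KRT6B at −1.95 and −2.51 and −1.05 and −2.00. Of its 16 genes, 4 were at least 2-fold lower and 3 passed adjusted over the list alone.

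Interferon-stimulated genes and genes of the ATF4 amino acid response were higher mainly in the library labelled shRNA 2. Of 38 interferon-stimulated genes, 34 were at least 2-fold higher with shRNA 2 and 8 with shRNA 1, with medians of 2.16 and 0.38. The antiviral genes RSAD2 and CMPK2 had log2 folds of 1.61 and 1.36 with shRNA 1 and 4.21 and 3.87 with shRNA 2, while SAMD9L and SAMD9 had 2.52 and 1.77 and then 3.27 and 2.39. Of 29 ATF4-linked genes, 25 were at least 2-fold higher with shRNA 2 and 6 with shRNA 1, with medians of 1.80 and 0.44. The cystine transporter gene SLC7A11 stood at 1.99 and 4.78, the serine synthesis gene PSAT1 at 1.44 and 3.70, and CHAC1 and CTH at 3.60 and 4.07 and at 2.73 and 3.53. All 4 medians lay above all 10000 random lists. The difference between the hairpins has no replicate check, since each hairpin has 1 library, and edgeR passed 1 interferon gene and 2 ATF4-linked genes adjusted over the lists alone and none over all genes.

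Several other groups differed between the hairpin libraries. The 30 mitosis genes had medians of 0.09 with shRNA 1 and −0.79 with shRNA 2, with MKI67 at 0.40 and −0.47 and TOP2A at 0.43 and −0.70. The 15 genes of the mitochondrial genome had 0.08 and −1.02, with MT-CO1 at 0.23 and −0.47, and MT-RNR2 had 112716 counts in the control, 130428 with shRNA 1 and 63981 with shRNA 2. Glycolysis genes had −0.22 and −0.87 (PKM −0.10 and −1.02, ENO1 −0.20 and −0.60), and nuclear genes of oxidative phosphorylation 0.08 and −0.33 (ATP5A1 0.59 and −0.18, ATP5B −0.07 and −0.65). With shRNA 2 these 4 medians lay below at least 99% of random lists, and with shRNA 1 all 4 lay within the middle 95%. Inflammatory cytokine genes showed the opposite order, −1.21 with shRNA 1 (below all random lists) and 0.04 with shRNA 2. CCL2 (−4.11 and −4.18), TNF (−2.70 and −3.07) and CXCL6 (−2.04 and −1.57) were lower with both, and BIRC3 (2.05 and 1.47) was higher, with 3 of 24 genes passing adjusted over the list alone. No gene of the other lists in this paragraph passed, adjusted in either way.

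The p53 targets and the cholesterol synthesis genes moved apart. The 25 p53 targets had a median of −0.23 with shRNA 1 (percentile 0.94) and 0.92 with shRNA 2 (percentile 100), with GADD45A at −0.77 and 0.60 and the cell cycle inhibitor gene CDKN1A at −1.08 and 0.48. The 25 cholesterol synthesis genes had medians of 0.58 and −0.67 (percentiles 100 and 0). In that list STARD4 was lower with both hairpins (−1.35 and −1.93), and over both hairpins the list's median was −0.07 and its mean 0.06. No member of either list passed edgeR's test, even adjusted over the list alone.

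The lists that remain had smaller or mixed values. Ribosomal protein genes had medians of 0.16 and 0.09 (percentiles 99.7 and 99.1; RPLP0 0.37 and 0.34, RPL4 0.13 and 0.07) and nuclear-retained long non-coding RNAs 0.34 and 0.80, although the imprinted RNA MEG3 was lower (−2.17 and −2.46) and was the 1 member to pass adjusted over the list alone. Housekeeping genes had −0.21 and −0.61 (percentiles 2.35 and 0.04), with ACTB at −0.46 and −1.05 and B2M at −0.09 and 0.63. DNA replication genes had 0.05 and 0.02 (PCNA 0.14 and −0.01, MCM4 0.01 and −0.06). Immediate early genes had −0.03 and 0.43, with PHLDA1 (2.62 and 3.37) and EGR1 (1.94 and 1.97) higher and IER3 (−2.40 and −2.21) and FOSB (−2.41 and −1.98) lower, and 6 of 27 passed adjusted over the list alone. Heat shock genes had −0.03 and −0.50 (DNAJB4 −1.45 and −1.98), unfolded protein response genes −0.25 and 0.21 (HSPA5 −0.33 and 1.26, CANX −0.02 and 0.48) and NRF2-linked genes 0.28 and −0.01 (PIR 2.59 and 1.06). Apoptosis regulators had 0.05 and 0.27 (PMAIP1 1.84 and 2.32), replication histones 0.19 and 0.64 (HIST1H2AC 1.22 and 1.55), small RNA processing genes −0.07 and 0.14 (AGO2 −0.30 and 0.65, DICER1 0.31 and 0.85) and the neighbours of LINC00958 −0.13 and −0.33. No direction is given for lists whose sign depended on the scaling, which moves all genes alike: DNA replication and NRF2-linked genes with shRNA 2, heat shock, immediate early, small RNA and neighbouring genes with shRNA 1, and the H3K4 methyltransferase complex with both hairpins. The same holds for LINC00958 itself with shRNA 2.

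Markers of other cell types were sparsely counted. Of 14 leukocyte markers 4 were measured, with medians of −0.39 and 0.58; CD74 stood at 0.00 and 0.01, and ITGAM had 19 counts in the control, 6 with shRNA 1 and 288 with shRNA 2. Of 14 endothelial markers 6 were measured, with medians of −0.70 and 0.63, and PDPN (−3.87 and −3.59) and TIE1 (−2.47 and −2.20) were lower with both hairpins and passed adjusted over the list alone. Of all 34 lists, 13 lay outside the middle 95% of random lists in the same direction with both hairpins, 8 lower and 5 higher. The same random genes taken for both hairpins, which share the control gene by gene, put 0.321 of 34 lists there on average and 3 at most in 10000 sets. Genes that moved together in the lone control are not covered by this number. Neither are members shared between lists, such as TGFBI, CDH2 and COL1A1, since each random list was drawn separately. With shRNA 2 alone 21 lists lay outside, and with shRNA 1 alone 19.

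**Figure D3:**
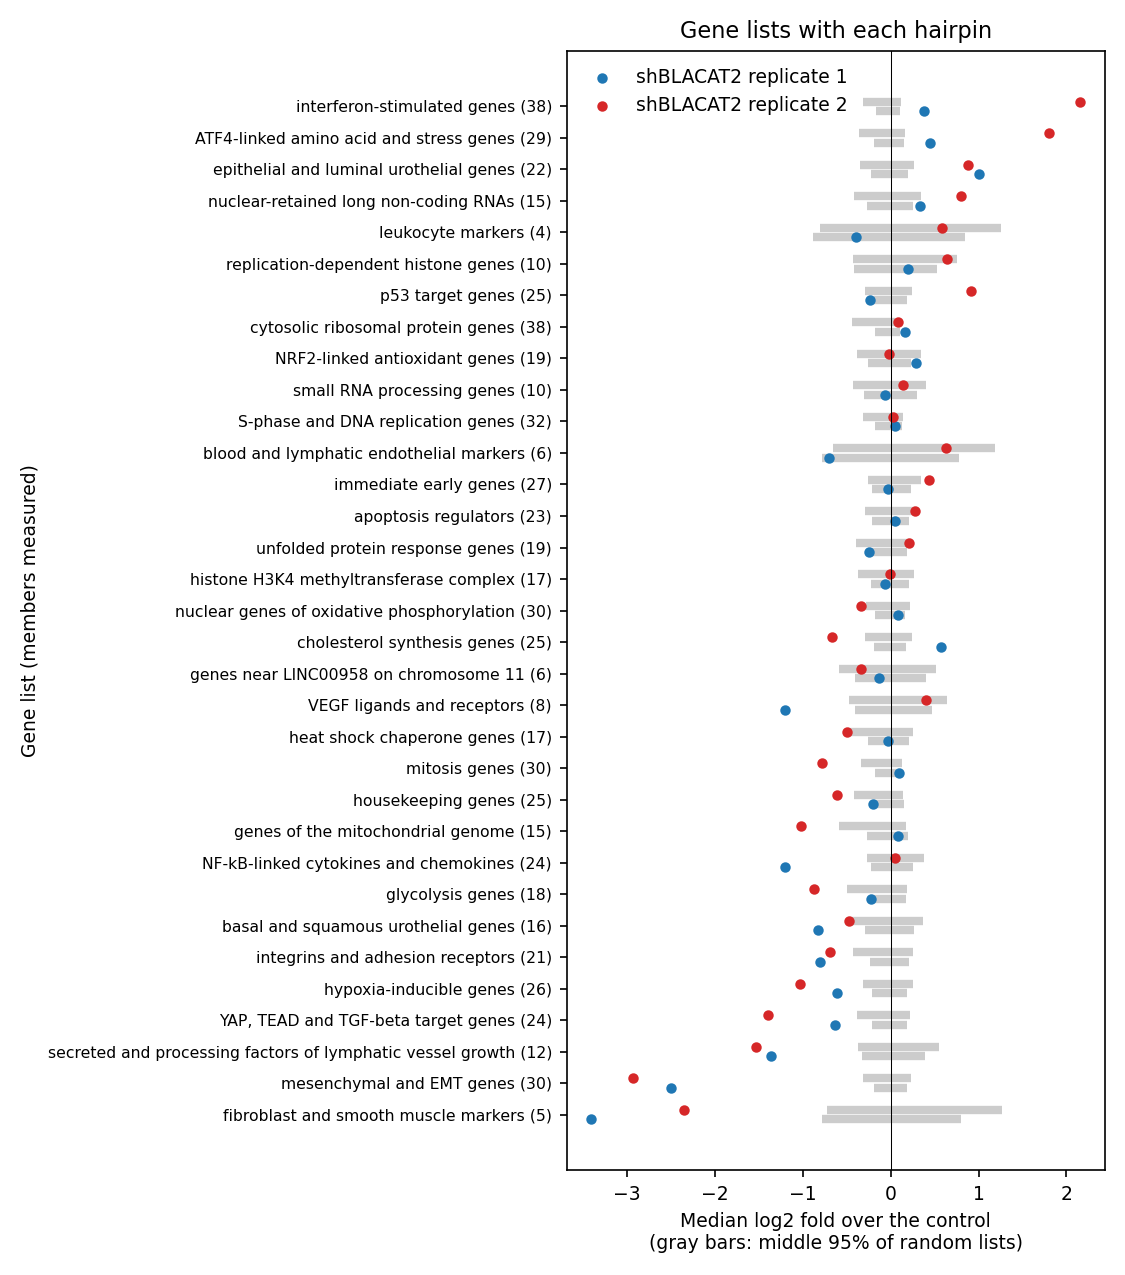
Median log2 fold over the control of each gene list with shRNA 1 (blue) and shRNA 2 (red), with the number of measured members in brackets and gray bars for the middle 95% of 10000 random lists matched on expression. The mesenchymal list lies at −2.50 and −2.93, and the interferon list at 0.38 and 2.16.

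The hairpin libraries were also compared with each other, which measures the spread inside the shBLACAT2 group. At least 2-fold differences between them were found for 1942 genes, 1264 higher and 678 lower with shRNA 2. VIM and SPARC differed in size but not in direction, VIM having 7583 counts in the control, 1061 with shRNA 1 and 154 with shRNA 2 (VIM and SPARC were chosen after their values were seen). SPARC had 42380, 11676 and 2401. Of the 1942 genes, 104 were at least 2-fold away from the control in opposite directions, 95 of them higher with shRNA 2.

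Agreement of the hairpins over genes was above the level simulated for a shared control that varied like the hairpin libraries. Across 15132 genes, which are not independent replicates, the log2 folds of both hairpins had a Pearson r of 0.680 and a Spearman rho of 0.587, against 0.499 (range 0.476 to 0.520) and 0.468 in 100 simulations of unchanged libraries that shared 1 control. The covariance was 0.625 against a simulated 0.311. VEGFC, MMP9 and INHBB were among the 1481 genes past 2-fold with both hairpins, against 814 (756 to 872) in the simulations and 253.1 for independent lists. The signs matched for 71.2% of genes, against 66.5%. The noise of the simulations was taken from the difference between the hairpin libraries. The lone control could not be split to take its own noise out. A control that varied more than the hairpin libraries would raise the simulated agreement. The excess can therefore not be told apart from noise of the lone control.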

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

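The p53 targets and the cholesterol synthesis genes stood out because their lists moved in opposite directions in the libraries of both hairpins. The p53 targets had a median log2 fold over the control of −0.23 with shRNA 1 and 0.92 with shRNA 2, and the median difference between the hairpins was 1.31. MDM2 had 1477 counts in the control, 1103 with shRNA 1 and 4298 with shRNA 2, and CDKN1A had 2593, 1452 and 4115. The cholesterol synthesis genes had medians of 0.58 and −0.67, with a median difference of −1.21. HMGCS1 had 1144, 3282 and 485 counts. MDM2 and HMGCS1 were chosen after their values were seen. The difference was not tested for either list, since each hairpin has 1 library, and no explanation was tested for it.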

How the results depend on the processing

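All settings described here were chosen before the data were examined. Of 51 recomputed summary values, 30 stayed near the reported value, and 21 moved. The numbers of genes by size moved with the filter and with the size asked for, as these settings take in more or fewer genes. Genes at least 2-fold away with both hairpins numbered 1481 as reported, 2805 without a low-expression filter, 979 with a mean of at least 5 CPM, 2967 at 1.5-fold and 631 at 3-fold. With the same filters in that order, the numbers were 5207 and 1428 for shRNA 1, 6820 and 2076 for shRNA 2 and 4434 and 1071 between the hairpins. The correlation of the hairpins was 0.617 without a filter and 0.731 at 5 CPM.

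The group test moved most between tools. Against 6 genes with edgeR, DESeq2 passed 531, and limma passed 0 (1560 at unadjusted p below 0.05). edgeR passed 0 without a filter (1461 at unadjusted p below 0.05) and 0 at 5 CPM (1240), where the smallest adjusted p was 0.0513. The cause of these differences was not tested. With either hairpin left out no residual degree of freedom remained, so no test was made, and the genes at least 2-fold away by 1 hairpin alone numbered 2315 to 3286. The lists outside the middle 95% of random lists numbered 13 with both hairpins and 19 to 21 with 1 hairpin, where a single library had to pass.

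DESeq2's size factors left 6 calls and 13 lists, prior counts of 0.5 and 5 left 13 lists, and a mean of at least 5 CPM left 10. For 129 named genes, 358 of 387 recomputed folds stayed within the spread between the hairpins, 29 moved beyond it (16 genes, by 1.98 at most on the log2 scale), and 1 fold of a gene that passed no test changed sign. Depth limits genes near 3 counts, or 0.198 TMM-scaled CPM in the control, where counting error alone spans several-fold.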

Other observations

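The explanations weighed in this part were all tested after the patterns had been seen, and the gene families, the genes of 1 hairpin and the further genes named here were also chosen after the data were seen.

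All 5 measured kallikrein genes were at least 2-fold higher with both hairpins, where the share of all protein-coding genes gives 0.25. KLK7 and KLK8, with 6 and 3 control counts, reached the filter's mean of 1 CPM only through the hairpin libraries. Their direction was thus partly fixed by the filter, as was that of EPGN below (4 control counts). Of 8 ligands of the EGF family 4 were higher, against 0.39: EREG (log2 folds 3.47 and 4.09), EPGN (4.13 and 3.41), BTC (2.93 and 3.15) and AREG (2.35 and 2.83). Mucins (3 of 7), claudins (3 of 10) and uroplakins (2 of 3) also held higher members and no lower ones. Of 26 collagen genes 10 were lower, against 1.23, and 2 were higher, and of 13 ADAMTS proteases and 10 tubulins 5 and 4 were lower. Lysyl oxidases (2 of 4) held lower members and no higher ones. With both hairpins, other families held members in both directions or few past that size: keratins (3 higher and 2 lower of 19), laminins (1 and 2 of 11), ligands of the TGF-beta superfamily (2 and 4 of 13), ephrins and their receptors (1 and 4 of 16), amino acid transporters (3 and 1 of 22), MHC class I genes (1 and 0 of 13) and tRNA synthetases (0 and 0 of 18). With shRNA 2 alone 7 of the 13 MHC class I genes (median 1.05) and 6 of the 18 tRNA synthetases (median 0.65) were at least 2-fold higher, against 1 and 0 with shRNA 1. INHBB was higher while INHBA had 8642 counts in the control and 1698 and 2517 with the hairpins. The cell cycle inhibitor gene CDKN2A had 3542, 1780 and 1402 counts in the control, shRNA 1 and shRNA 2 libraries, and CDKN2B had 3241, 374 and 297.

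Some genes differed from the control with 1 hairpin only, by at least 2-fold and with the other hairpin under 1.5-fold. With shRNA 2 these were 611 higher and 378 lower genes, and with shRNA 1 191 and 197. IFNL1 had 2, 4 and 156 counts, MUC2 25, 28 and 1009, GDF15 299, 375 and 4049, and the thioredoxin-binding gene TXNIP 1943, 2735 and 200. With shRNA 1, ID4 had 335, 3065 and 475 counts and NLRP1 484, 84 and 821.

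The first pattern weighed was that LINC00958 was not lower with shRNA 2. No order of the labels gives a halving in these counts, since the lowest library held 0.735 of the highest (counting interval 0.668 to 0.808). A swap of labels among the 3 libraries cannot be excluded by this. The control and shRNA 2 libraries held nearly the same level, and a loss hidden from the counts would leave no mark. A scaling that hides a halving was argued against, the lowest log2 fold over 3 scalings being −0.47. Reads from annotated exons outside the RefSeq transcript could hide a loss. This cannot be told apart from the absence of one because the counts are not given by position. Such exons make up 35.9% of the exon bases in GENCODE release 29. Their share in the annotation used for the counting is not known. A loss of the RNA that recovered, or that acts outside the polyA+ fraction, was not tested.

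The second pattern was the lower mesenchymal genes with both hairpins. A shift of the scaling by a few abundant genes was argued against. Without the 100 most abundant genes the median nearest to 0 was −2.52 (bootstrap over genes −3.56 to −1.52, 25 genes). Fibroblasts mixed into the control cells were argued against, because COL1A2, COL3A1, DCN and LUM together had 40 counts there against 5253 for COL1A1, a ratio of 0.00761 (0.00543 to 0.0104). A control of another cell line with other whole-chromosome copy numbers was argued against. The largest chromosome median shared by both hairpins was 0.149 in size (chromosome 12, widest bootstrap bound over genes 0.203). Gains or losses of parts of a chromosome were not examined, so another cell line as such is not excluded by this. A subclone of UM-UC-3, another cell line without whole-chromosome differences, a batch of the lone control, shared off-target effects and an effect of BLACAT2 depletion remain open and untested.

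The third pattern was that interferon-stimulated and ATF4-linked genes were higher with shRNA 2 than with shRNA 1. A trend with transcript GC content and length was argued against. After that trend was removed, the smaller of both lists' median differences was 1.32 (bootstrap over genes 1.09 to 1.95, 29 genes). A few abundant genes were argued against in the same way, with 1.49 (bootstrap over genes 1.36 to 1.92, 37 genes) without the 100 most abundant genes. Whether the response grows with a loss of LINC00958 cannot be told apart from other causes: that RNA had a ratio of 1.36 for shRNA 2 over shRNA 1 (interval 1.24 to 1.49), but the interval covers counting error only and each hairpin has 1 library. An effect of the shRNA 2 hairpin or its virus, which may include a response to double-stranded RNA, remains open and was not tested.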
